A study of Mus musculus with 12 samples.

How the data were processed

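The measurements were RNA-seq counts per gene in 12 tumours, 3 in each of 4 treatment groups. Per the labels' protocols, Sq-1979 squamous carcinoma cells mixed with Matrigel were injected under the skin of male C3H/HeN mice, tumour RNA was isolated with a column kit, and libraries came from a stranded, poly(A)-based TruSeq kit. Doses, treatment times and the hour of tumour collection were not given in the sources used here. The labels number the tumours 1 to 3 in each group without saying that each came from a separate mouse, so p-values measure the spread between these samples, part of which may be technical.

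Per the submitters' processing notes, reads were trimmed with cutadapt 2.4 and aligned with STAR 2.7.2a to GRCm38. The counting program, its strand setting and the annotation release were not given in the sources used here. The deposited values were whole-number counts, not normalized, for 54446 Ensembl gene identifiers in each of 12 columns. Because the strand setting was unknown, values of genes that overlap another gene or an antisense transcript, and of families with near-identical members such as the guanylate-binding proteins, the Ifi200 genes, the Oas1 genes and the H2 genes, are uncertain in their division between members. Identifiers were matched without their version to GENCODE release M21 on GRCm38 for gene symbols, positions, exonic length and GC content. Of these, 54409 matched and 37 did not. Columns were assigned to tumours by the sample code that each label gives.

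Total counts ran from 21088288 to 28512141 per tumour. Genes with too few counts for testing were removed with edgeR's filterByExpr, which left 16833 genes holding at least 99.9% of the counts in each tumour. Libraries were scaled with TMM factors, which ran from 0.970 to 1.026. CPM values, counts scaled to these library sizes, are given as mean ± SD over 3 tumours. Each 2 tumours of a group were compared with a chi-square test over genes with a summed count of at least 20. The lowest statistic was 11.8 per degree of freedom, so no pair agreed within counting noise and all 12 were kept as separate samples.

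The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with a mean for each group, robust dispersion estimates and all 12 tumours in one fit. It covered 5 pairwise comparisons, the SN-38 and the antibody effect each averaged over the other treatment, and their interaction, which is the antibody effect with SN-38 minus that without it. P-values were adjusted by Benjamini and Hochberg's method over the genes tested, with a threshold of 0.05. Fold changes are log2 values with their SE, and every adjusted p printed for a gene comes from this test unless another is named. The test was tried on simulated counts before use. With 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold between SN-38 and vehicle, it recovered 22.4%, 58.2% and 87.9% of them, with 7 unchanged genes called among 16630. For the SN-38 effect averaged over antibody status, the shares were 59.7%, 85.1% and 93.9%, with 10 unchanged genes called among 16624. DESeq2 called 48 unchanged genes in each of these simulations.

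Before the data were examined, 38 gene lists were fixed, covering interferon responses, antigen presentation, immune, stromal and epithelial cell types, the cell cycle, DNA damage, stress and drug handling. Of these, 36 had at least 5 genes tested. Each was tested with limma's camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data and with fry, each adjusted over the 36 lists. The list test was tried on a simulated shift of 0.5 in 1 list between SN-38 and vehicle. All 3 tests recovered it, and none called another list. The simulated genes were drawn independently of each other, so this trial cannot show how often correlated genes lead to false list calls. Counts of list members past 0.05 are also given adjusted over the list alone. A list score is the mean log2 CPM of its members in a tumour. Scores were compared for each treatment by an exact two-sided permutation test within the strata of the other treatment, over 400 assignments, whose smallest possible p is 0.005. For 3 tumours against 3, the exact test cannot go below 0.1. Added after the data were seen were 5 further lists, of E-box clock genes, Bmal1-phase clock genes, glucocorticoid-induced genes, follicular B cells and Y-linked genes.

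Genes named in the text followed a rule fixed before the data were examined. Where genes passed the threshold, the rule took the 5 largest changes in each direction with a mean log2 CPM of at least 1 and no overlap between groups. Where none passed, it took the 3 smallest p-values in each direction, as values that did not pass. From up to 8 lists with the smallest adjusted camera p, it took the 3 members with the smallest p in the list's direction. In pairwise comparisons it added Cd274, Pdcd1, Cd8a, Gzmb, Ifng, Ncr1, Cdkn1a, Mki67, Top1, Cxcl9, Cxcl10 and H2-K1. Unnamed predicted genes and pseudogenes were passed over. Of the genes that this rule names, 1 is not reported here. Col1a1 and Csf3, the further genes shown in figures (Dbp and Foxp3) and the genes of the closing section were chosen after their values were seen.

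The alternatives were DESeq2's size factors for scaling, no filter on low counts, DESeq2 1.42.0, limma voom with sample weights, fits with only the compared groups, the replicate number as a block, a minimum absolute log2 fold change of 1, and each tumour left out in turn. An offset for exonic length and GC content, a fit without the tumours numbered 3 of both antibody groups, and a fit without SN-38 tumour 1 and combination tumour 2, were added after the data were seen.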

Results

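Gene expression was measured in 12 subcutaneous tumours of the mouse line Sq-1979, which the labels describe as a head and neck squamous cell carcinoma. The mice received vehicle, a rat antibody against the T-cell inhibitory receptor PD1, SN-38, or the antibody with SN-38, with 3 tumours in each of the 4 groups. SN-38 is the metabolite of irinotecan that inhibits topoisomerase I. By its title, the series concerns a gain in anti-PD1 efficacy from SN-38. Total counts were 23780420, 27446371 and 25681506 in vehicle tumours 1 to 3, 23387238, 26546722 and 28044825 with anti-PD1, 26931148, 28228937 and 25142121 with SN-38, and 24838491, 21088288 and 28512141 with the combination.

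By correlation, tumours of one group were no more alike than tumours of different groups. The median correlation of log2 CPM was 0.979 within groups and 0.981 between groups. Of the first 5 principal components, which held 36.7%, 17.9%, 10.8%, 7.45% and 5.73% of the variance, 24.0%, 42.1%, 23.1%, 34.7% and 54.1% lay between groups, where 27.3% would come by chance. The pieces differed in stroma and immune content. Col1a1, a collagen chain made by fibroblasts, ranged from 2411 CPM in anti-PD1 tumour 1 to 25996 CPM in SN-38 tumour 2. Anti-PD1 tumour 3 and combination tumour 3 had the highest T-cell scores of the 12, 3.998 and 4.21 mean log2 CPM, against 2.52 to 3.24 in the other 10. SN-38 tumour 1 and combination tumour 2 had the highest neutrophil scores, 3.62 and 3.54, against 0.02 to 1.69 in the rest, and held 10.7 and 24.1 CPM of Csf3, a neutrophil growth factor, against at most 2.22 CPM elsewhere. These tumours and genes were singled out after their values were seen.

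Against vehicle, 2 of the 3 tumours given anti-PD1 alone had higher values of interferon-gamma induced genes and of T-cell, NK-cell and checkpoint genes, and all 3 had lower values of cell-cycle genes, but no gene passed the threshold. Anti-PD1 tumour 2 lay within the range of the vehicle tumours, with interferon-gamma, T-cell, NK-cell and checkpoint scores of 6.54, 2.6997, 0.52 and 3.84 against 6.06 to 6.97, 2.67 to 2.88, 0.49 to 0.72 and 3.67 to 3.97 (exact permutation p = 0.3, 0.3, 0.3 and 0.2 for the groups). All 24 interferon-gamma response genes had higher means, with a median log2 difference of 0.73. Type I interferon genes were higher in 28 of 34 cases with a median of 0.12 and did not pass by camera (adjusted p = 0.0535). Gbp2b, a guanylate-binding GTPase, stood at 833 ± 392 CPM against 374 ± 99.2 in vehicle (log2 difference 1.16 ± 0.42 SE, adjusted p = 0.844), and Gbp2 and Igtp differed by 0.90 ± 0.35 and 0.76 ± 0.30. Cd274, which encodes the PD1 ligand PD-L1, stood at 155.0 ± 74.3 CPM against 68.9 ± 22.4.

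Of 21 T-cell genes, 20 had higher means with anti-PD1. Cd8a, the CD8 co-receptor of cytotoxic T cells, stood at 23.5 ± 7.5 against 14.9 ± 1.4 CPM, and Cd3d at 8.0 ± 3.7 against 3.6 ± 0.9 CPM. All 15 NK-cell genes had higher means, among them Klrc1, Eomes and Cd226 with log2 differences of 0.97, 0.83 and 0.84. The cytotoxic effectors Prf1 and Gzmb, a pore-forming protein and a granule protease, differed by 0.99 ± 0.43 and 1.20 ± 0.68. Pdcd1, the gene of PD1 itself, differed by 1.08 ± 0.46, and its second ligand gene Pdcd1lg2 by 2.47 ± 0.86, with 4.5 ± 3.9 against 0.8 ± 0.1 CPM. Tox, a factor of exhausted T cells, differed by 1.27 ± 0.50. The MHC class I presentation genes Nlrc5, Tap1 and H2-T23 differed by 0.48, 0.32 and 0.33. In the other direction, all 26 DNA replication genes and all 24 G2/M genes had lower means. Of 10 mitochondrially encoded genes 9 were lower, with a median of -0.22 (adjusted p = 0.00669 by camera and adjusted p = 0.827 with an estimated correlation), and of -0.13 without anti-PD1 tumour 1 (adjusted p = 0.0839) or vehicle tumour 3 (adjusted p = 0.0288). E2f1, Ccne2 and Mcm7 differed by -0.58, -0.47 and -0.27, and the mitotic genes Ccnb2, Ube2c and Kif23 by -0.56, -0.50 and -0.53. Without anti-PD1 tumour 3 the T-cell, NK-cell, cytotoxic effector, class I and checkpoint lists no longer passed by camera (adjusted p = 0.172, 0.213, 0.376, 0.214 and 0.363), and with all tumours none of these lists passed at an estimated correlation (adjusted p = 0.827 with an estimated correlation). Ifng, Ncr1, Cdkn1a, Mki67, Top1, Cxcl9, Cxcl10 and H2-K1 also did not pass. The smallest p-values belonged to Cblb, a ubiquitin ligase that restrains T-cell activation (0.90 ± 0.14, adjusted p = 0.702), Med13l and Rapgef6, which were higher, and Fjx1, Gnl3 and Shox2, which were lower.

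For anti-PD1 against vehicle, edgeR called 0 of 16833 genes, with 943 at an unadjusted p below 0.05, where 842 would come by chance. DESeq2 called 28 genes, Cblb among them (DESeq2 adjusted p = 2.33e-05), and limma voom 0. By camera with the preset correlation, 16 of 36 lists passed, 8 higher and 8 lower, and 8 passed without anti-PD1 tumour 3. Among the lower lists were fibroblasts, with 21 of 22 genes lower and a median of -0.29 that was 0.09 without anti-PD1 tumour 1 (adjusted p = 0.951) and -0.56 without anti-PD1 tumour 3. Differentiated squamous epithelium, with 12 of 15 genes lower and a median of -0.37, did not pass without vehicle tumour 1 or 2 or anti-PD1 tumour 1 or 3 (adjusted p = 0.0508, 0.0655, 0.0847 and 0.102). None passed with an estimated correlation (interferon-gamma response and cell-cycle G2/M, adjusted p = 0.827 with an estimated correlation), and no member of these lists passed over all genes or adjusted over the list alone.

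**Figure D1:**
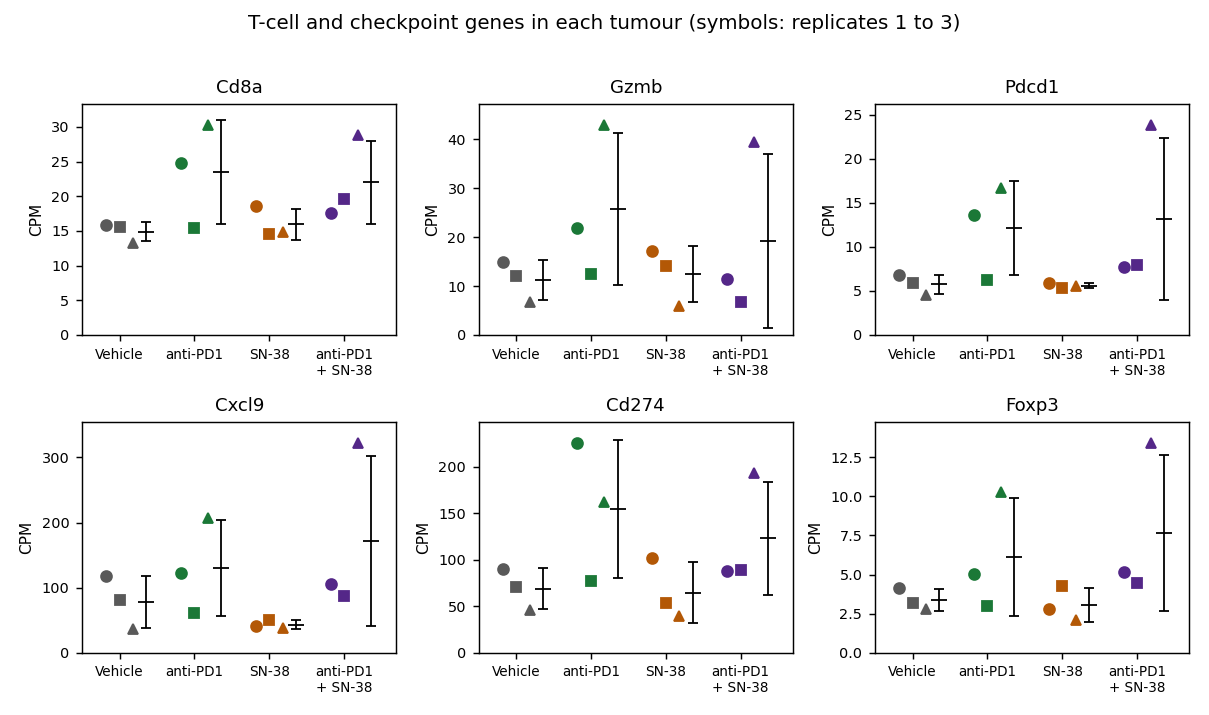
CPM of Cd8a, Gzmb, Pdcd1, Cxcl9, Cd274 and Foxp3 (vertical axes) in each tumour of the 4 groups (horizontal axis), with replicates 1 to 3 as circle, square and triangle and the mean ± SD of 3 tumours in black. In all panels but that of Cd274, tumour 3 of each antibody group had the highest value of its group, for example 42.9 and 39.5 CPM of Gzmb.

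SN-38 alone was accompanied by lower values of type I interferon genes and by a rise of the repressor gene Mnt. Mnt, which competes with Myc for its partner Max, rose from 35.2 ± 1.4 to 54.3 ± 1.7 CPM (log2 fold change 0.63 ± 0.07 SE, adjusted p = 0.0339) and was the one gene that passed. Mnt (ENSMUSG00000000282.12) lies on chromosome 11 at 74830920 to 74845725 on the plus strand of GRCm38. All 34 type I interferon response genes had lower means with SN-38, with a median of -0.49. Isg15, a ubiquitin-like protein, stood at 61.7 ± 3.3 against 108 ± 7.4 CPM, the nucleotide kinase Cmpk2 at 21.4 ± 5.3 against 45.3 ± 4.5 CPM, and the antiviral GTPase Mx2 at 41.0 ± 5.9 against 58.7 ± 2.0 CPM. The score of this list was 6.57 ± 0.11 in SN-38 tumours and 7.08 ± 0.09 in vehicle tumours without overlap, where the exact permutation test of 3 against 3 cannot go below its p of 0.1. In this comparison 3 of 36 list scores did not overlap, against 10% (3.6 lists) by chance.

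The interferon-gamma response genes were also lower, in 22 of 24 cases, with Socs1, Ifi47 and Ido1 at -0.72, -0.48 and -1.42. Cxcl10, a chemokine that attracts activated T cells, stood at 51.0 ± 10.4 against 115 ± 31.4 CPM (-1.18 ± 0.41, adjusted p = 0.401). Proliferation genes were lower on average, in all 26 DNA replication and all 24 G2/M genes, with Fen1 at -0.43, Cdc45 at -0.42, E2f1 at -0.50, Ccnb2 at -0.56, Ube2c at -0.54 and Ttk at -0.53. SN-38 tumour 1 had the lowest G2/M score of the 12, 5.36, against 5.99 and 6.32 in the other SN-38 tumours and 6.09 to 6.43 with vehicle. The medians of the replication and G2/M lists, -0.35 and -0.33, were -0.13 for both without SN-38 tumour 1 and -0.62 and -0.57 without SN-38 tumour 3. Of 26 DNA damage repair genes, 19 had lower means, among them H2afx at -0.55, the checkpoint kinase gene Chek1 at -0.62 and Fanca at -0.32. Cdkn1a, the p53-induced cell-cycle inhibitor, stood at 70.9 ± 27.2 against 84.3 ± 6.6 CPM, and Top1, the drug's target, at 92.9 ± 5.1 against 95.5 ± 6.4 CPM. Lower too were the immediate-early genes Ier2, Egr1 and Jund (-0.50, -0.64 and -0.35), the stress-response genes Herpud1, Atf3 and Asns (-0.32, -0.73 and -0.39), and the muscle genes Mb, Tnni2 and Myh1 (-0.61, -1.13 and -1.39). With 1 tumour left out, calls by camera ended for interferon-gamma response without vehicle tumour 1 or SN-38 tumour 2 or 3 (adjusted p = 0.387, 0.0805 and 0.294), and for DNA damage repair without vehicle tumour 2 or SN-38 tumour 1 (adjusted p = 0.109 and 0.648). The calls of the early response and stress-response lists ended without SN-38 tumour 2 (adjusted p = 0.0805 and 0.373). With all tumours no list passed at an estimated correlation, where the smallest adjusted p was 0.987. Cd274, Pdcd1, Cd8a, Gzmb, Ifng, Ncr1, Mki67, Cxcl9 and H2-K1 did not pass.

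For SN-38 against vehicle, 1690 genes had an unadjusted p below 0.05, DESeq2 called 166 and limma voom 1. The call of Mnt ended when any 1 of the 6 tumours was left out, with a log2 fold change of 0.59 to 0.65 and an adjusted p of 0.243, 0.176 and 0.446 without vehicle tumour 1, 2 and 3 and of 0.169, 0.134 and 0.168 without SN-38 tumour 1, 2 and 3. It also ended at an adjusted p of 0.112 without the filter on low counts and 0.206 with only the 2 groups in the fit, and held with limma voom (adjusted p = 0.0229) and with DESeq2. Of the 34 type I interferon genes, with edgeR 0 passed over all genes and 13 adjusted over the list alone. That count was 0 without vehicle tumour 1, 2 or 3, or without SN-38 tumour 1 or 3, and 28 with only the 2 groups in the fit. By camera 8 lists passed, all lower, and none with an estimated correlation (type I interferon response, cell-cycle G2/M and DNA replication, adjusted p = 0.987 with an estimated correlation).

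**Figure D2:**
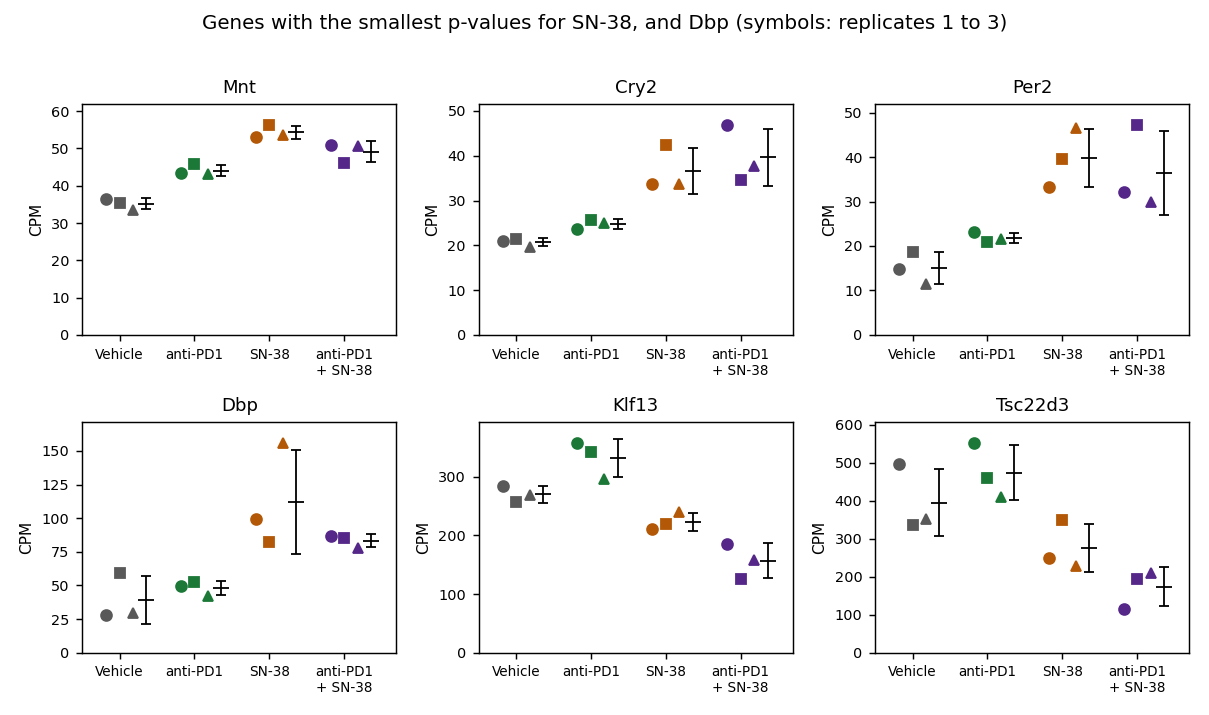
CPM (vertical axes) of Mnt, Cry2, Per2, Dbp, Klf13 and Tsc22d3 in each tumour of the 4 groups (horizontal axis), with replicates 1 to 3 as circle, square and triangle and the mean ± SD of 3 tumours in black. The 6 tumours given SN-38 held 33.7 to 46.8 CPM of Cry2 and the other 6 held 19.6 to 25.7 CPM.

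In tumours given anti-PD1 and SN-38 together, the core clock repressors Cry2 and Per2 were higher than in vehicle tumours and the zinc-finger factor Klf13 lower, without a gene past the threshold. Cry2 stood at 39.7 ± 6.4 against 20.7 ± 0.9 CPM (log2 difference 0.94 ± 0.13, adjusted p = 0.195), Per2 at 36.4 ± 9.4 against 15.0 ± 3.6 CPM (1.28 ± 0.21, adjusted p = 0.265) and Mnt at 49.2 ± 2.7 against 35.2 ± 1.4 CPM. Klf13 stood at 157 ± 29.8 against 270.0 ± 14.2 CPM (-0.78 ± 0.13), Herpud1 at 164 ± 12.2 against 230.2 ± 13.7 CPM, and the phosphatase gene Dusp14 at 14.9 ± 1.5 against 29.01 ± 2.1 CPM.

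All 22 fibroblast and matrix genes had lower means with the combination, with a median of -0.69, and Tagln, Lum and Sparc differed by -1.09, -1.65 and -1.09. Of 18 muscle genes, 17 were lower, Mb, Tnni2 and Casq1 by -0.63, -1.20 and -1.30, and 13 of 15 genes of differentiated squamous epithelium were lower, Sprr1a by -0.81, Dsc2 by -0.36 and Sbsn by -0.34. Combination tumour 2 had a muscle score of -0.85 against 3.59 and 3.17 in the other 2, and the median of the muscle list, -1.13, was -0.57 without it and -0.72 without vehicle tumour 3 (exact permutation p = 0.2 for the scores). The squamous list no longer passed by camera without combination tumour 2 (median -0.18 rather than -0.48, adjusted p = 0.0715) or 3 (adjusted p = 0.0684). Endothelial genes were higher in 14 of 16 cases, Cdh5 by 0.51 ± 0.15, Flt1 by 0.45 ± 0.15 and Plvap by 0.35 ± 0.12, and the list median of 0.30 was 0.18 without combination tumour 2. Immune genes were higher on average, with T-cell scores of 2.89, 2.86 and 4.21 against 2.67 to 2.88 in vehicle. Without combination tumour 3 the interferon-gamma, T-cell, macrophage and class II lists no longer passed by camera (adjusted p = 0.372, 0.551, 0.313 and 0.486), nor did the first without vehicle tumour 3 (adjusted p = 0.0605). With all tumours no list passed at an estimated correlation, where the smallest adjusted p was 0.845. Ciita, the master regulator of MHC class II, stood at 187 ± 76.3 against 93.9 ± 30.1 CPM, and H2-DMb2, H2-DMa, Gbp4 and Irf8 differed by 1.08, 0.69, 1.14 and 0.92. Cd3d and Cd8a differed by 1.07 and 0.57, and the macrophage receptors Mertk, Msr1 and Siglec1 by 1.18, 0.77 and 1.07. Pdcd1 and Ifng differed by 1.20 ± 0.46 and 1.34 ± 0.49, and the other genes fixed in advance did not pass either.

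For the combination against vehicle, edgeR called 0 genes, with 2164 at an unadjusted p below 0.05 and a smallest adjusted p of 0.195, while DESeq2 called 173 and limma voom 1, which was Cry2 (adjusted p = 0.0239). By camera 19 lists passed, 16 higher and 3 lower, and 6 passed without combination tumour 3. None passed with an estimated correlation (fibroblasts, skeletal muscle, interferon-gamma response and endothelium, adjusted p = 0.845 with an estimated correlation). No member of these 4 lists passed with edgeR over all genes or adjusted over the list alone.

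Adding SN-38 to the antibody was accompanied by lower Klf13, Pik3r1 and Tsc22d3 and by higher cell-cycle, endothelial and inflammatory genes than with the antibody alone. Klf13 stood at 157 ± 29.8 against 332 ± 32.0 CPM (-1.08 ± 0.13, adjusted p = 0.107), Pik3r1, a regulatory subunit of PI3-kinase, at 173 ± 6.2 against 300.3 ± 32.8 CPM (-0.79 ± 0.12, adjusted p = 0.178), and Tsc22d3, which glucocorticoids induce, at 173 ± 51.3 against 474 ± 71.7 CPM (-1.45 ± 0.25). Tenm4 (0.99 ± 0.15), Glt1d1 (1.04 ± 0.16) and Wsb1 (0.51 ± 0.08) had the smallest p-values among genes with higher values. All 24 G2/M genes had higher means, Cenpe, Kif23 and Ttk by 0.60, 0.56 and 0.47, as had 25 of 26 DNA replication genes, Pole, Pold1 and Rrm2 by 0.52, 0.27 and 0.35. Among endothelial genes 15 of 16 were higher, Plvap by 0.40 ± 0.12, Tie1 by 0.49 ± 0.16 and Emcn by 0.61 ± 0.25. Of 21 inflammatory cytokine genes 20 were higher, Lif by 0.49 ± 0.15, Ptgs2, the inducible prostaglandin synthase, by 2.20 ± 0.69 and the neutrophil chemokine Cxcl5 by 2.82 ± 1.01. Cxcl3 and Mmp8 of the neutrophil list differed by 2.82 and 1.32, the DNA sensors Aim2 and Cgas by 0.56 ± 0.11 and 0.25 ± 0.15, the kinase gene Ikbke by 0.23, the repair genes Fanca, Rad54l and Atr by 0.44, 0.50 and 0.18, and the muscle genes Mb, Myh2 and Tnni2 by -0.57, -1.06 and -0.60. Type I interferon genes did not pass by camera, with 21 of 34 higher and a median of 0.05 (adjusted p = 0.321). Without combination tumour 2 the muscle and neutrophil lists no longer passed (medians of -0.10 and 0.87 rather than -0.60 and 1.70, adjusted p = 0.872 and 0.330). Nor did the replication list without anti-PD1 tumour 1 (adjusted p = 0.0688), or the DNA sensing list without anti-PD1 tumour 1 or 2 or combination tumour 3 (adjusted p = 0.0688, 0.103 and 0.410). With all tumours no list passed at an estimated correlation, where the smallest adjusted p was 0.950. None of the 12 genes fixed in advance passed, and Cd8a, Gzmb and Cd274 had log2 differences of -0.09, -0.42 and -0.33.

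For the combination against anti-PD1, edgeR called 0 genes with 1340 at an unadjusted p below 0.05, DESeq2 76 and limma voom 0. Klf13 passed without the filter on low counts (adjusted p = 0.00724) and Tenm4 without combination tumour 3 (adjusted p = 0.0271). By camera 10 lists passed, 9 higher and 1 lower, against 18 without anti-PD1 tumour 3 and 16 without combination tumour 1. None passed with an estimated correlation (cell-cycle G2/M and endothelium, adjusted p = 0.950 with an estimated correlation).

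Adding the antibody to SN-38 was accompanied by higher values of type I interferon genes in all 34 cases, with a median log2 difference of 0.72. Against vehicle the combination was not clearly higher, with scores of 7.26 ± 0.29 and 7.08 ± 0.09 that overlapped (exact permutation p = 0.5). The median against vehicle, 0.23, was 0.04 without combination tumour 3 (adjusted p = 0.874 by camera). Ifih1, a sensor of double-stranded RNA, stood at 115 ± 3.8 against 80.9 ± 5.2 CPM (0.50 ± 0.10, adjusted p = 0.618), and the oligoadenylate synthetases Oas3 at 190.2 ± 38.6 against 101 ± 9.3 CPM and Oas1g at 40.01 ± 4.8 against 24.0 ± 2.7 CPM. With edgeR 0 of the 34 passed over all 16833 genes, and 33 passed adjusted over the list alone. DESeq2 called members over all genes, among them Oas3, Ifih1, Cmpk2, Usp18, Rsad2 and Isg15 (DESeq2 adjusted p = 0.0162, 0.0242, 0.0246, 0.0282, 0.0346 and 0.0482). The list scores did not overlap, 7.26 ± 0.29 with the combination and 6.57 ± 0.11 with SN-38 alone, where the exact permutation test of 3 against 3 cannot go below its p of 0.1, and 8 of 36 list scores did not overlap in this comparison, against 10% (3.6 lists) by chance. The list passed by camera, with an adjusted p = 0.420 with an estimated correlation, and 18 members passed adjusted over the list alone without SN-38 tumour 3 or without combination tumour 3.

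**Figure D3:**
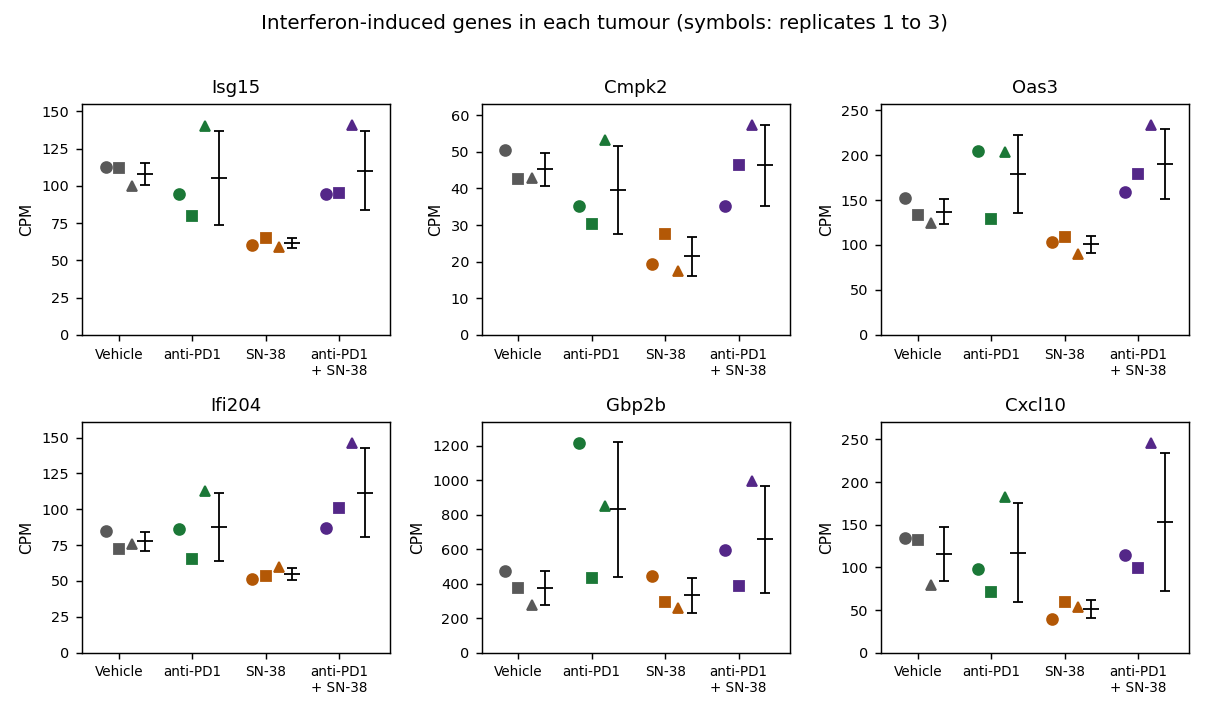
CPM (vertical axes) of Isg15, Cmpk2, Oas3, Ifi204, Gbp2b and Cxcl10 in each tumour of the 4 groups (horizontal axis), with replicates 1 to 3 as circle, square and triangle and the mean ± SD of 3 tumours in black. Isg15 stood at 59.2 to 65.4 CPM in the 3 SN-38 tumours and at 80.0 CPM or more in the other 9.

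All 24 interferon-gamma response genes were higher with the combination than with SN-38, with a median of 0.83 (0.52 without combination tumour 3). By edgeR 0 of them passed over all genes or adjusted over the list alone. Cxcl9 stood at 172 ± 131 against 42.9 ± 6.9 CPM (2.0 ± 0.60, adjusted p = 0.618), Cxcl10 at 153 ± 80.5 against 51.0 ± 10.4 CPM and Cxcl11 at 52.9 ± 29.7 against 14.6 ± 1.6 CPM; these 3 chemokines bind Cxcr3, a chemokine receptor of activated T cells and NK cells. The medians of the recruiting chemokine and class II lists, 1.02 and 0.68, were 0.41 and 0.27 without combination tumour 3. Ido1, Gbp3 and Ccl3 differed by 2.41, 0.82 and 1.23. Of 10 cytosolic DNA sensing genes 9 were higher, with Ifi204 at 1.02 ± 0.21 and Ikbke at 0.32 ± 0.09. Adjusted over the list alone 6 passed, and 2, 3 and 1 without SN-38 tumour 1, SN-38 tumour 2 and combination tumour 3. Among inflammatory cytokines Lif, Ccl20 and Ccl2 differed by 0.58, 1.08 and 1.53. The immunoproteasome genes Psme1, Psmb10 and Psme2 differed by 0.49, 0.72 and 0.42, the class II genes H2-DMb2, Ciita and H2-DMa by 1.32, 1.0 and 0.85, and the G2/M genes Ttk, Kif23 and Cenpe by 0.51, 0.48 and 0.43. The G2/M median of 0.31 was 0.07 without SN-38 tumour 1, 0.19 without combination tumour 1 and 0.56 without SN-38 tumour 3. Mlkl, the executioner of necroptosis, had the smallest p (0.74 ± 0.12, adjusted p = 0.618), followed among higher genes by Slc25a25 and Phf11d, and Pik3r1, Atrn and Gclc, a subunit of the enzyme that starts glutathione synthesis, were lower by -0.69, -0.38 and -0.64. Pdcd1, Ifng and Ncr1 differed by 1.24 ± 0.46, 1.37 ± 0.49 and 1.5 ± 0.70, and none of the 12 genes fixed in advance passed.

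For the combination against SN-38, edgeR called 0 genes with 1334 at an unadjusted p below 0.05, DESeq2 50 and limma voom 0. By camera 23 of 36 lists passed, 20 higher and 3 lower, and none with an estimated correlation, where the smallest adjusted p was 0.420. T-cell genes were higher in 20 of 21 cases with a median of 0.76, which was 0.09 without combination tumour 3 (adjusted p = 0.300). Without that tumour the cytotoxic effector, NK-cell and dendritic cell lists did not pass either (adjusted p = 0.214, 0.771 and 0.0524). Fibroblast genes were lower in 21 of 22 cases with a median of -0.70, which was 0.28 without SN-38 tumour 2 (adjusted p = 0.691), and they did not pass without combination tumour 2 (adjusted p = 0.402). The other lower lists were basal and differentiated squamous epithelium, with medians of -0.15 and -0.26. The first did not pass without SN-38 tumour 1 or 3 or combination tumour 2 or 3 (adjusted p = 0.150, 0.132, 0.322 and 0.329), nor the second without SN-38 tumour 3 or combination tumour 2 or 3 (adjusted p = 0.240, 0.992 and 0.111).

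**Figure D4:**
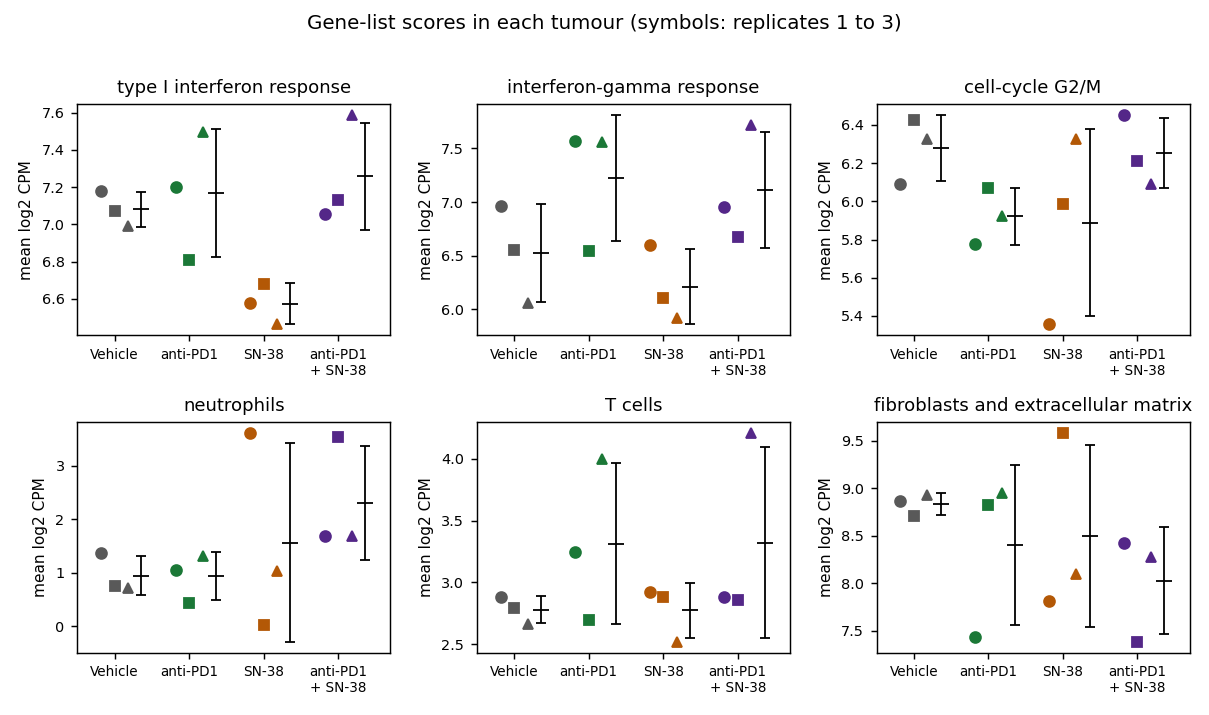
Mean log2 CPM of the members of 6 gene lists (vertical axes, not starting at 0) in each tumour of the 4 groups (horizontal axis), with replicates 1 to 3 as circle, square and triangle and the mean ± SD of 3 tumours in black. The type I interferon score lay between 6.46 and 6.68 in SN-38 tumours and between 6.81 and 7.59 in the others.

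Over both antibody states, 6 tumours with SN-38 against 6 without, Cry2 and Per2 were higher and Klf13 lower without overlap, and each missed the threshold. Cry2 differed by 0.75 ± 0.09 and Mnt by 0.39 ± 0.05 (both adjusted p = 0.0528), Per2 by 1.07 ± 0.15 and Klf13 by -0.68 ± 0.09 (both adjusted p = 0.0764), Tent5b by -0.65 and Tsc22d3 by -0.98. By antibody state, without and with it, Cry2 differed by 0.82 and 0.68, Per2 by 1.41 and 0.74, Mnt by 0.63 and 0.16, and Klf13 by -0.27 and -1.08. The interaction for Mnt was -0.47 ± 0.10 (adjusted p = 0.597), and it passed with DESeq2 (adjusted p = 0.00934). Type I interferon genes were lower in 33 of 34 cases, Rtp4, Ifi27l2a and Ifit1 by -0.30, -0.26 and -0.44, and interferon-gamma genes in 21 of 24, Ifi47, Tgtp2 and Socs1 by -0.45, -0.37 and -0.47. The type I median was -0.49 for SN-38 against vehicle and 0.05, with 21 of 34 genes higher, for the combination against anti-PD1. The interaction that tests this contrast had a median of 0.50 (0.27 without anti-PD1 tumour 2 and 0.28 without combination tumour 3) and did not pass with an estimated correlation (adjusted p = 0.510 with an estimated correlation). Endothelial genes were higher in 15 of 16 cases, Cdh5 by 0.30 and Plvap by 0.24, and neutrophil-list genes in 13 of 14, Mmp8 by 1.32, Cxcl3 by 2.48 and Ptgs2 by 1.34. Muscle genes were lower in 17 of 18 cases, Mb by -0.59, Tnni2 by -0.86 and Myh2 by -1.01, fibroblast genes in 18 of 22, Thy1 by -0.37, Tagln by -0.47 and Lum by -0.74, and early response genes in 13 of 20, Jund by -0.41, Egr1 by -0.47 and Ier2 by -0.29. The neutrophils list, with a median of 1.33, did not pass without SN-38 tumour 1 (0.60, adjusted p = 0.078) or without combination tumour 2 (1.20, adjusted p = 0.152), and its median was -0.03 without both. The interferon-gamma list did not pass without vehicle tumour 1, anti-PD1 tumour 1 or 3, SN-38 tumour 3 or combination tumour 1 or 2 (adjusted p of 0.0562 to 0.205). The fibroblast list did not pass without vehicle tumour 3, anti-PD1 tumour 2 or 3, SN-38 tumour 1 or 3 or combination tumour 2 (adjusted p of 0.0528 to 0.250), nor the early response list without vehicle tumour 2 or 3, anti-PD1 tumour 1, SN-38 tumour 2 or 3 or combination tumour 1 or 3 (adjusted p of 0.0562 to 0.339). With all tumours no list passed at an estimated correlation, where the smallest adjusted p was 0.996.

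For SN-38 averaged over antibody status, edgeR called 0 genes with 1764 at an unadjusted p below 0.05, DESeq2 201 and limma voom 1, which was Cry2. Cry2, Per2 and Klf13 passed without the filter on low counts (adjusted p of 0.0147 for the smallest), Cry2 and Klf13 without combination tumour 1, and Cry2 and Mnt without combination tumour 2. By camera 7 lists passed, 2 higher and 5 lower, against 11 without combination tumour 3, and none with an estimated correlation, where the smallest adjusted p was 0.996. In exact stratified permutation tests of the list scores, the smallest p was 0.05, for endothelium, which was higher by 0.20 with 5 of 6 tumours above the median of the others, with an adjusted p of 0.995 over 36 lists.

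Over both SN-38 states, 6 tumours with the antibody against 6 without, all 34 type I interferon and all 24 interferon-gamma response genes had higher means, with medians of 0.41 and 0.79. The type I median was 0.12 without SN-38, where the list did not pass, and 0.72 with it. Oas3 differed by 0.65 ± 0.13 (adjusted p = 0.732), Ifih1 by 0.32 ± 0.07 and Eif2ak2, the double-stranded RNA kinase, by 0.22 ± 0.06. Gbp4 differed by 1.23 ± 0.34, Gbp2b by 1.07 ± 0.30 and Igtp by 0.76 ± 0.21. T-cell genes were higher in 20 of 21 cases, Cd8a by 0.56, Cd3d by 0.97 and Cd247 by 0.84, NK-cell genes in all 15, Klre1 by 1.20, Klrc1 by 0.69 and Eomes by 0.70, and cytotoxic effectors in 14 of 16, Prf1 by 1.09, Klrg1 by 1.68 and Ifng by 1.17. Among antigen presentation genes Nlrc5, Psme1 and Tap1 differed by 0.49, 0.34 and 0.36, and Ciita, H2-DMb2 and H2-DMa by 0.93, 0.91 and 0.66. The chemokine genes Ccl4, Cxcl11 and Ccl3 differed by 0.83, 1.16 and 0.82. Mitochondrially encoded genes were lower in 8 of 10 cases, with a median of -0.14 (adjusted p = 0.0102 by camera and adjusted p = 0.477 with an estimated correlation). They did not pass without anti-PD1 tumour 1 (adjusted p = 0.0715), SN-38 tumour 3 (median -0.07, adjusted p = 0.124), or combination tumour 1 or 3 (adjusted p = 0.0670 and 0.0617). Inpp1 had the smallest p (0.31 ± 0.06), Ifi203 was higher by 0.46, and Shox2, Dusp14 and Eci1 were lower by -0.53, -0.44 and -0.19.

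For the antibody averaged over SN-38 status, edgeR called 0 genes with 1123 at an unadjusted p below 0.05, DESeq2 14 and limma voom 0. The DESeq2 calls, made over all genes, included Oas3, Ifi203, Ifih1, Gbp4 and Gbp2b (DESeq2 adjusted p = 0.0238, 0.0268, 0.0404, 0.0404 and 0.0493). With edgeR no interferon gene passed over all genes. By the same test 28 of the 34 type I and 22 of the 24 interferon-gamma genes passed adjusted over the list alone. The first count was 0 without anti-PD1 tumour 3, 16 without vehicle tumour 3 and 17 without SN-38 tumour 3 or combination tumour 3, and the second was 14 without combination tumour 3. Both were 0 with limma voom, and 0 without the tumours numbered 3 of both antibody groups, which had the highest T-cell scores. By camera 19 lists passed, 15 higher and 4 lower, and none with an estimated correlation, where the smallest adjusted p was 0.388. The medians of the T-cell, NK-cell and cytotoxic effector lists, 0.72, 0.70 and 0.79, were 0.42, 0.37 and 0.36 without combination tumour 3, and the last 2 were 0.46 and 0.47 without anti-PD1 tumour 3. Besides the mitochondrially encoded genes, 3 lists were lower. Fibroblast genes were lower in 21 of 22 cases, with a median of -0.49 that was -0.01 without SN-38 tumour 2 (adjusted p = 0.0734), and genes of differentiated squamous epithelium in 14 of 15, with a median of -0.24 that was -0.13 without combination tumour 2 (adjusted p = 0.0668). Muscle genes were lower in 15 of 18 cases with a median of -0.26, and did not pass without vehicle tumour 3, anti-PD1 tumour 2, SN-38 tumour 2 or 3, or combination tumour 2 (adjusted p = 0.0958, 0.199, 0.0530, 0.191 and 0.265), with a median of 0.05 without SN-38 tumour 3. In exact stratified permutation tests of the scores, interferon-gamma response differed by 0.80 (p = 0.025, 6 of 6 tumours above the median of the others), immune checkpoints by 0.55 (p = 0.015, 5 of 6) and type I interferon by 0.39 (p = 0.035, 5 of 6), each with an adjusted p of 0.22 over 36 lists.

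The antibody effect with SN-38 minus that without it was positive for all 34 type I interferon genes and all 24 G2/M genes, with medians of 0.50 and 0.66, and no gene passed. The first was 0.27 without anti-PD1 tumour 2 and 0.28 without combination tumour 3, and the second 0.43 without SN-38 tumour 1, which had the lowest G2/M score of the 12. The scores of both lists with the combination lay near those with vehicle, 7.26 against 7.08 for type I interferon and 6.25 against 6.28 for G2/M. Cmpk2, Rsad2 and Usp18 had interaction values of 1.31 ± 0.34, 1.62 ± 0.43 and 0.76 ± 0.22. Usp18, which removes Isg15 from proteins, stood at 166 ± 8.2, 160.0 ± 29.7, 112 ± 7.2 and 182 ± 34.6 CPM with vehicle, anti-PD1, SN-38 and the combination. Ttk, Ccnb2 and Kif23 had values of 1.0, 0.95 and 1.01, and Pold1, Cdc45 and Mcm10 of the replication list 0.52, 0.68 and 0.95. The repair genes Fanca, H2afx and Chek1 had values of 0.76, 0.76 and 0.88, the inflammatory genes Lif, Ccl20 and Nfkb2 0.75, 1.24 and 0.48, the DNA sensing genes Ikbke, Ifi204 and Aim2 0.45, 0.84 and 0.43, the endothelial genes Egfl7, Tie1 and Eng 0.57, 0.52 and 0.47, and the amino acid stress genes Shmt2, Asns and Chac1 0.41, 0.61 and 1.08. The endothelial list did not pass without anti-PD1 tumour 2 or SN-38 tumour 3 (adjusted p = 0.0517 and 0.117), nor the stress list without SN-38 tumour 2 (adjusted p = 0.137). With all tumours no list passed at an estimated correlation, where the smallest adjusted p was 0.510. Gclc, Pik3r1 and Cblb had the smallest p-values, with negative values of -1.18 ± 0.18, -1.11 ± 0.17 and -1.22 ± 0.19 (each adjusted p = 0.313). All of these passed with DESeq2 (DESeq2 adjusted p = 2.52e-05, 1.80e-05 and 2.81e-05). Cblb stood at 80.7 ± 11.1, 150.3 ± 18.5, 134 ± 13.0 and 107 ± 13.4 CPM with vehicle, anti-PD1, SN-38 and the combination. Mlkl, Cth and Gtse1 had values of 0.75, 0.83 and 0.93.

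For the interaction, edgeR called 0 genes with 1284 at an unadjusted p below 0.05, DESeq2 24 and limma voom 0. By camera 13 lists passed, all positive, against 8 without anti-PD1 tumour 2, and none with an estimated correlation (cell-cycle G2/M and type I interferon response, adjusted p = 0.510 with an estimated correlation).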

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

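The tests for glucocorticoid-induced genes and for a lower share of tumour cells were chosen after the results were seen, as was the rule that the latter hold with each tumour left out, and the test for the hour of collection after Per2, Cry2, Per3 and Nr1d2 had been seen. For 13 lists the antibody effect with SN-38 differed from that without it, by camera on the interaction with the preset correlation. The median log2 differences were 0.66 for cell-cycle G2/M, 0.54 for DNA replication, 0.50 for type I interferon response, 0.91 for inflammatory cytokines, 0.26 for DNA damage repair, 0.49 for cytosolic DNA sensing, 0.26 for endothelium, 0.24 for the unfolded protein response, 0.47 for T-cell recruiting chemokines, 0.19 for p53 targets, 0.35 for early response genes, 0.62 for dendritic cells and 0.41 for macrophages. None passed with an estimated correlation, where the adjusted p ran from 0.510 to 0.973, and 62 of 100 splits of the tumours gave at least the 13 lists, the highest other 26, so chance is not excluded. With 1 tumour left out, the value for type I interferon was 0.27 without anti-PD1 tumour 2 and 0.28 without combination tumour 3, for G2/M 0.43 without SN-38 tumour 1, and for replication 0.34 without SN-38 tumour 1 and 0.82 without SN-38 tumour 3. For inflammatory cytokines it was 0.44, 0.58 and 0.54 without SN-38 tumour 2, SN-38 tumour 3 and combination tumour 2, and for DNA sensing 0.27 without combination tumour 3. For chemokines, macrophages and dendritic cells it was 0.17, 0.23 and 0.30 without anti-PD1 tumour 2, and 0.91, 0.82 and 1.02 without anti-PD1 tumour 3. For p53 targets it was 0.08, 0.29 and 0.06 without SN-38 tumour 2, SN-38 tumour 3 and combination tumour 2. For the unfolded protein response it was 0.15 without anti-PD1 tumour 1, and for early response genes 0.23 without vehicle tumour 3. The lists of chemokines, macrophages, dendritic cells, endothelium, p53 targets, the unfolded protein response and early response genes each stopped passing without at least 1 tumour, and without combination tumour 3 the values for chemokines, macrophages and dendritic cells were 0.18, 0.06 and -0.15 (adjusted p = 0.330, 0.382 and 0.552). No gene was called in the interaction, so all 100 of 100 splits gave at least the real 0 (highest other 42), an outcome fixed beforehand that says nothing on chance. Groups of 3 are too small for the test for a single distant sample, and no column lay outside the comparisons.

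Clock genes differed between tumours with and without SN-38, and a difference in the hour of collection is a candidate explanation: it would move the E-box genes and the Bmal1-phase genes in opposite directions, and the first, a list that holds the 4 genes already seen, were higher by 0.53 (0.76 without the antibody and 0.30 with it), and the second differed by -0.20 (exact stratified permutation p = 0.01, adjusted p = 0.025), made of -0.28 without the antibody and -0.11 with it (exact p = 0.1 and 0.2). Cry1 was higher by 0.54 and Per1 differed by -0.50, which a plain shift in phase leaves unexplained. Glucocorticoid-induced genes differed by -0.093 (exact permutation p = 0.395), by 0.14 without the antibody (exact p = 0.3) and -0.33 with it (exact p = 0.1). Members went both ways. Tsc22d3, Klf9 and Pdk4 differed by -1.0, -0.53 and -0.75 (exact p = 0.01, 0.025 and 0.045, adjusted p = 0.0571, 0.0833 and 0.12). Zbtb16, Ddit4 and Errfi1 differed by -0.52, -0.26 and -0.25 (exact p = 0.24, 0.095 and 0.12), and Mt1 and Mt2 by -0.12 and -0.10. Lcn2 had the largest rise, 1.82 (exact p = 0.075, adjusted p = 0.176), and Sult1a1, Cebpd, Fkbp5 and Sgk1 were higher by 0.05 to 0.23. The rise of Lcn2 thus pulls the list mean up against members that were mostly lower, and glucocorticoid exposure stays open. Cry2, Per2 and Mnt kept 96.8% to 99.7% of their log2 differences with an offset for length and GC content, which argues against such a bias as the whole cause. An effect of SN-38 on the clock stays open, and tumours collected at recorded hours would test it.

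Immune genes were higher on average in tumours given the antibody. In exact stratified permutation tests, T-cell genes differed by 0.54 (p = 0.1), fibroblast genes by -0.45 (p = 0.305) and endothelial genes by 0.083 (p = 0.34). None of these differences stood by itself. T-cell minus fibroblast scores differed by 0.99 (exact stratified permutation p = 0.045). With 1 tumour left out the 0.99 became 0.75 to 1.25, with an exact p of 0.015 to 0.09 that was below 0.05 only without anti-PD1 tumour 2, SN-38 tumour 1 or combination tumour 1; the T-cell value was 0.32 without combination tumour 3, and the fibroblast value -0.21, -0.18 and -0.29 without anti-PD1 tumour 1, SN-38 tumour 2 and combination tumour 2. The p of 0.045 for the 0.99 would by itself argue against a lower share of tumour cells, which would raise all 3. By the rule added afterwards that share stays open, as does lymphoid tissue in the tumour piece. Follicular B-cell genes were higher by 0.41, and B-cell minus T-cell genes came to -0.13 (exact permutation p = 0.555). An antibody effect on infiltration may contribute and would need counts of T cells in sections of more tumours.

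Many of the genes with the lowest p-values against vehicle were long, with a median exonic length of 10.05, 7.82 and 5.86 kb in the top 100 for anti-PD1, SN-38 and the combination, against 3.85 kb for all genes. The correlation of the log2 difference with exonic length was 0.0996, 0.215 and 0.119 (Spearman rho). The smallest lies just under the bound of 0.1 set for the absence of a length bias, closer than its spread, and the allowance for that spread was added after the value was seen. Mitochondrially encoded genes, whose share can vary with RNA quality, had medians of -0.22, 0.06 and -0.03 in these comparisons. A difference in RNA quality or library preparation could give such a trend and is not told apart here from a treatment effect. The comparisons with vehicle all use the same vehicle tumours, so they are not independent of each other. For the combination against anti-PD1 and against SN-38, where vehicle has no part, the median length in the top 100 was 4.17 and 4.07 kb. The rho there was 0.043 and -0.070.

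Other splits of the tumours were counted for each result. For 3 tumours against 3 there are 10 splits, too few for a share under 0.05. For anti-PD1 against vehicle, 6 of 10 gave at least the 16 lists (highest other 22) and all 10 of 10 at least 0 genes (highest other 0). For SN-38 against vehicle, 10 of 10 gave at least 8 lists (highest other 20) and 1 of 10 the 1 gene (highest other 0). For the combination, 3 of 10 gave at least 19 lists against vehicle (highest other 21), 8 of 10 at least 10 lists against anti-PD1 (highest other 23) and 3 of 10 at least 23 lists against SN-38 (highest other 26), and 10 of 10 gave at least 0 genes in each (highest other 0). Of 100 splits for SN-38 averaged over antibody status, 95 gave at least 7 lists (highest other 26), and for the antibody averaged over SN-38 status 26 gave at least 19 lists (highest other 27), so chance is not excluded for these list counts. All 100 gave at least 0 genes in both (highest other 543 and 3). Where the real count is 0 every split reaches it, which says nothing on chance. The splits with 543 and 137 genes for SN-38 averaged point to a structure among the tumours. The first set vehicle tumours 1 and 3, anti-PD1 tumours 2 and 3, SN-38 tumour 2 and combination tumour 3 against the rest, with fibroblast scores, looked up afterwards, of 8.28 to 9.59 against 7.38 to 8.71; what lies behind it was not tested.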

How the results depend on the processing

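The length and GC offset and the fits without tumours 3 of both antibody groups or without SN-38 tumour 1 and combination tumour 2 were chosen after the data were seen. Of 4551 values of named genes under the alternatives, 4485 kept their direction and 68 passed the threshold. Of the medians of up to 8 lists with the smallest p per comparison, 682 kept their direction and side of the threshold and 62 kept their direction but no longer passed. The 1 of these that reversed was the neutrophils median log2 fold change, SN-38 averaged over anti-PD1 status, at -0.029 (adjusted p = 0.871) without SN-38 tumour 1 and combination tumour 2, against 1.33; under the other alternatives its adjusted p ran from 2.36e-05 to 0.152. Among all lists that passed, leaving out 1 tumour also turned the sign of fibroblasts for anti-PD1 against vehicle (0.09 without anti-PD1 tumour 1), cytotoxic effectors and NK cells for the combination against vehicle and macrophages for it against anti-PD1 (-0.15, -0.17 and -0.13 without combination tumour 3). Against SN-38 it turned fibroblasts (0.28 without SN-38 tumour 2) and neutrophils (-0.12, -0.11 and -0.99 without SN-38 tumour 2, SN-38 tumour 3 and combination tumour 2). It turned muscle for the antibody averaged (0.05 without SN-38 tumour 3) and dendritic cells for the interaction (-0.15 without combination tumour 3), and none of these passed then. With DESeq2 the genes called were 28, 166, 173, 76 and 50 in the pairwise comparisons (anti-PD1, SN-38 and the combination against vehicle, the combination against anti-PD1 and against SN-38), 201 and 14 for SN-38 and the antibody averaged, and 24 for the interaction; in simulations DESeq2 called 48 unchanged genes. For SN-38 against vehicle the 1 call became 0 with a minimum log2 fold change of 1, since Mnt changed less, without the filter on low counts, with only the compared groups in the fit, without SN-38 tumour 1 and combination tumour 2 together, and without any 1 tumour (0 to 0). With limma voom, 1 gene was called for the combination against vehicle and 1 for SN-38 averaged; without the filter, 1 for the combination against anti-PD1 and 3 for SN-38 averaged; with the length and GC offset, 1 for SN-38 averaged. Leaving out 1 tumour gave 0 to 1 genes for the combination against anti-PD1 and 0 to 2 for SN-38 averaged. The list counts were 0 in all 8 comparisons with an estimated correlation and with fry. Without tumours 3 of both antibody groups 9 lists passed for anti-PD1 against vehicle and 5 for the combination against vehicle. Leaving out 1 tumour gave 8 to 19 lists for anti-PD1 against vehicle, 6 to 20 for the combination against vehicle, 8 to 18 for the combination against anti-PD1, 5 to 11 for SN-38 averaged and 8 to 18 for the interaction. The type I interferon genes past the threshold over the list alone, 13 for SN-38 against vehicle, were 28 with only the compared groups, 0 without SN-38 tumour 1 and combination tumour 2 together, and 0 to 10 without 1 tumour. For the combination against SN-38 they were 20 without tumours 3 of both antibody groups and 18 to 33 without 1 tumour. For the antibody averaged they were 0 with limma voom, 0 without tumours 3 and 0 to 33 without 1 tumour, and the interferon-gamma genes 0, 0 and 14 to 23. Fewer tumours lower the power of a test; otherwise the cause was not tested. Where 1 tumour is left out, a group keeps 2, and its spread is pooled with that of the other groups.

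The replicate numbers do not pair the tumours. Over 18 pairs with the same number in different groups the median correlation was -0.05 (-0.47 to 0.63), and 4 of 12 tumours correlated best with one of their own number. With the number as a replicate block, the 1 call for SN-38 against vehicle became 0 (adjusted p = 0.142 for Mnt).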

Other observations

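The values of single genes in this part were chosen after they were seen, while the test of long genes was set before its result. SN-38 tumour 1 and combination tumour 2 had the highest scores of the neutrophil list. S100a8 and S100a9, which form calprotectin, stood at 23.1 and 45.3 CPM in SN-38 tumour 1 and at 16.8 and 35.3 CPM in combination tumour 2, against at most 2.47 and 5.16 CPM elsewhere. Counts from whole tumour pieces do not show which cells made these transcripts. Combination tumour 2 held 0.28 CPM of the muscle actin Acta1, against 17.5 to 141 CPM in the others, and the lowest values of the basal keratins Krt14 and Krt5, 1635 and 4411 CPM. Igkc, an antibody light chain made by B-lineage cells, stood at 41.5 and 51.2 CPM in anti-PD1 tumour 3 and combination tumour 3, against 0.998 to 12.8 CPM elsewhere.

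Among clock genes, Dbp, a target of the clock, was higher with SN-38 by 1.17 and Nr1d2 by 0.33, each without overlap between 6 and 6 tumours (exact stratified permutation p = 0.005, the smallest possible, adjusted p = 0.05), and Arntl, which encodes Bmal1, differed by -0.30 (p = 0.02, adjusted p = 0.0727). Trp63, the squamous lineage factor, stood at 410 to 537 CPM over the 12 tumours and Sox2 at 55.7 to 76.9 CPM. Xist, expressed from the inactive X, stood at 410 to 1173 CPM and the Y-linked gene Ddx3y at 10.1 to 19.4 CPM. The mice were male, and male cells normally have no inactive X, which argues against host cells as the source of Xist. The sex of origin of the line was not given in the sources used here, so the Y-linked values cannot be assigned to line or host. In exact stratified permutation tests the Y-linked genes differed by 0.03 with SN-38 (p = 0.91) and by -0.01 with the antibody (p = 0.96), and the follicular B-cell genes by -0.08 with SN-38 (p = 0.815). With the antibody, by the same exact permutation test, E-box clock genes differed by -0.02 (p = 0.895), Bmal1-phase genes by -0.07 (p = 0.24) and glucocorticoid-induced genes by 0.17 (p = 0.15), made of 0.40 against vehicle (exact p = 0.1) and -0.06 against SN-38 (exact p = 0.7).

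Topoisomerase I relieves the strain of transcription along long genes, so its inhibition by SN-38 could lower long genes more than short ones. The slope of log2 CPM on log10 gene span differed by 0.0040 between tumours with and without SN-38 (exact stratified permutation p = 0.88). Across genes, the log2 difference correlated with gene span at a Spearman rho of 0.122 for SN-38 against vehicle, -0.0246 for the combination against anti-PD1 and 0.0774 for SN-38 averaged, so in the first and last longer genes tended to be higher, against the hypothesis. The rho was 0.0795 for anti-PD1 against vehicle, where no SN-38 was given. That comparison shares its vehicle tumours with SN-38 against vehicle, so it cannot tell whether such a trend is specific to the drug. The averaged values do not favour the hypothesis, which stays open because the dose and time of collection are unknown. A shorter interval after dosing would test it.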
